A study of Rattus norvegicus with 11 samples.

How the data were processed

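RNA was measured in the right ventricle of Sprague Dawley rats given monocrotaline or vehicle, with 5 monocrotaline and 6 vehicle libraries. Per the labels' protocols, the right ventricle was cut away from the left ventricle and vessels, total RNA was depleted of ribosomal RNA, and stranded libraries were sequenced on an Illumina NextSeq instrument. The submitters' processing notes name bcl2fastq, FastQC, cutadapt, HISAT2 and StringTie. Tool versions, the genome build, the annotation release and the strand setting used in counting are not given in the sources used here.

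The authors deposited a table of whole-number read counts with no normalization, holding 37550 features, of which 29682 carried an Ensembl rat gene ID and 7868 were loci assembled from the reads. Each column of counts was assigned to its library by the sample title, and 0 columns belonged to other samples. The second deposited table is the authors' own comparison of both groups, with a log fold change, a log CPM, a p-value and an FDR per row, per the file headers. The test and tool behind that table are not given in the sources used here. The fold changes and CPM values that the authors deposited there were on a log2 scale. The fold changes were found to be log2 monocrotaline over vehicle by setting them beside fold changes computed from the counts, with a slope of 0.999 across features. Its 16646 rows were the 16646 features with at least 1 CPM in at least 3 libraries, and its FDR column equalled a Benjamini-Hochberg adjustment of its p-values.

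Neither table pairs its IDs with gene names, and 0 IDs matched the RefSeq gene table of the GRCr8 assembly used here. The 38 gene lists and cell type markers fixed before the data were examined, among them the mitochondrial, fibrotic, inflammatory and angiogenic lists, were therefore not analysed here, and neither were their set tests. The rule for named genes, also fixed before, asked for genes with a symbol. It was applied instead to Ensembl IDs and shortened to 2 IDs each way: an FDR under 0.05, an average log2 CPM of at least 1, groups that did not overlap in CPM, and the largest log2 fold changes among these. No position or function is given for an ID, and reads shared between near-identical copies or overlapping genes were not examined.

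The main test was the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with robust dispersion and quasi-likelihood estimates, TMM factors, the filterByExpr defaults (minimum count 10, minimum total count 15), no covariate and Benjamini-Hochberg adjustment at an FDR of 0.05. The filter left 15099 features. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. CPM values used TMM-scaled library sizes, and log2 CPM values for principal components used a prior count of 2. Measures with 1 value per library were compared by exact two-sided permutation of the 462 possible splits. Tested on simulated counts for 14948 features, the edgeR step recovered 10.4% of 67 features changed 1.5-fold, 65.2% of 66 changed 2-fold and 90.9% of 66 changed 4-fold, with 4 false calls among 114. The simulated set held far fewer changed features than were called in the data, so its threshold on the unadjusted p was stricter and these shares do not carry over to the real comparison.

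Total counts ran from 9581924 to 14438355 per library. No library was a copy of another: over the 55 pairs, the lowest chi-square per degree of freedom was 15.5 across features with a mean count of at least 10. The labels do not state whether each library came from its own animal, so p-values measure the spread between these libraries.

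A score along the group difference was computed for each library from the other 10, as its projection on the line from the vehicle mean to the monocrotaline mean in log2 CPM, with 0% at the vehicle mean and 100% at the monocrotaline mean. The score carries no test of the difference between the groups. The rule for large gaps, given under the flagged results, was applied to the score and singled out no library. Libraries with reads in more than 25000 features were set apart as a detection class, a boundary chosen after seeing the data.

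The alternatives fixed before the data were examined were relative log expression and upper quartile factors, TMM without the 20 most abundant features, DESeq2 1.42.0, limma-voom with limma 3.58.1, no filter, a stricter filter (1 CPM in at least 5 libraries and a mean count of 50), an FDR of 0.01, a test against a minimum fold of 1.5, thinning to the smallest total, leaving out each library, and the replicate number as a block. Removing mitochondrially encoded genes along with the 20 was planned, but those genes could not be told from their IDs. Alternatives chosen after seeing the data were the 8 libraries of lower detection alone, the detection class as a covariate, library totals with no normalization factor, and the authors' filter.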

Results

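The right ventricular transcriptome was compared between rats given monocrotaline, a plant alkaloid that injures the lung vessels of rats and raises the pressure against which the right ventricle pumps, and rats given vehicle. The comparison addresses which transcripts differ in the right ventricle in this model of pulmonary arterial hypertension. There were 6 vehicle libraries, numbered 1 to 6, and 5 monocrotaline libraries, numbered 1, 2, 3, 4 and 6. Total counts averaged 11060506 ± 1889494 in the vehicle group (SD, n = 6) and 11638690 ± 1286044 in the monocrotaline group (SD, n = 5), which did not differ by an exact permutation test (p = 0.567). Assembled loci took 32.4% ± 1.20 of the counts with vehicle (SD, n = 6) and 32.4% ± 1.73 with monocrotaline (SD, n = 5). The features below are Ensembl gene IDs or loci assembled from the reads, and the files do not pair the IDs with gene names.

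Transcripts of the right ventricle differed widely between the groups, in both directions. Of 15099 features tested with edgeR, 1917 were higher and 1678 lower with monocrotaline at an FDR of 0.05, which is 23.8% of those tested. The median log2 fold change was 0.82 among the higher features and −0.72 among the lower. Changes of more than 2-fold were seen in 721 higher and 441 lower features, changes of more than 4-fold in 118 and 66, and changes of more than 8-fold in 22 and 9. Under 1.5-fold were 546 of the higher and 569 of the lower features. In 906 features every monocrotaline library lay above every vehicle library, and in 744 every one lay below. Together these were 10.9% of the features, against 0.433% for chance splits. Without a normalization factor the split became 3541 higher and 986 lower, and the median log2 fold change of the tested features moved from −0.01 to 0.21, so directions are relative to TMM scaling. The TMM factors themselves followed treatment without overlap. They were 0.937 ± 0.0211 with vehicle (SD, n = 6) and 1.086 ± 0.112 with monocrotaline (SD, n = 5; exact permutation p = 0.00216, adjusted p = 0.00649). With the 8 libraries of lower detection described below, 4 in each group, 1087 features were higher and 653 lower, a comparison with fewer libraries.

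**Figure D1:**
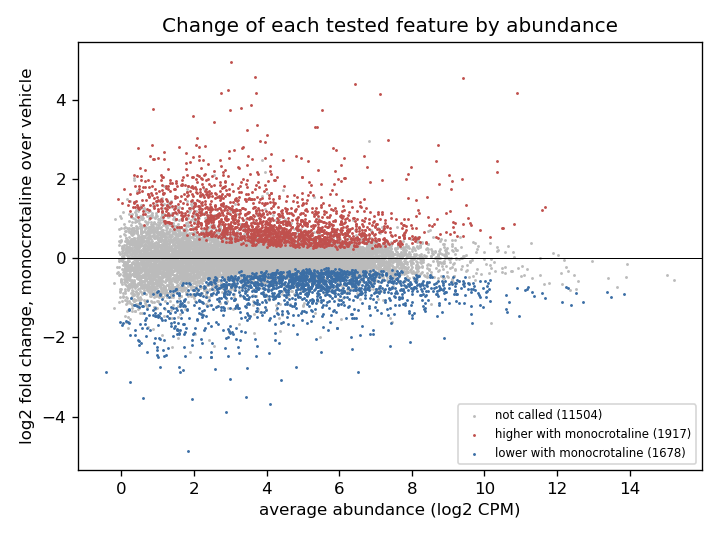
Log2 fold change of monocrotaline over vehicle against average abundance in log2 CPM for each of the 15099 tested features, one point per feature. Red points are the 1917 features called higher and blue points the 1678 called lower at an FDR of 0.05, and 77 of the 100 most abundant features lie below 0.

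The 2 Ensembl IDs with the largest rise by the fixed rule changed more than 20-fold. ENSRNOG00000012660 rose from 59.95 ± 38.1 CPM with vehicle (SD, n = 6) to 1419 ± 636 CPM with monocrotaline (SD, n = 5), a log2 fold change of 4.56 with SE 0.49 (edgeR, Benjamini-Hochberg adjusted p = 4.06e-04). It lay between 29.2 and 131 CPM in the vehicle libraries and between 413 and 1942 CPM in the monocrotaline libraries. ENSRNOG00000012471 rose from 8.52 ± 9.81 CPM (SD, n = 6) to 180 ± 103 CPM (SD, n = 5), with a log2 fold change of 4.40 and SE 0.75 (edgeR, adjusted p = 0.00288). Its vehicle replicate 5 stood at 27.7 CPM, against 9.23 CPM for the next vehicle library, and its lowest monocrotaline value was 66.7 CPM. Without vehicle replicate 5 its log2 fold change was 5.27, and in the 8 libraries of lower detection, which also leave that replicate out, it was 5.29.

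The 2 IDs with the largest fall were of low abundance. ENSRNOG00000012458 fell from 12.6 ± 4.66 CPM (SD, n = 6) to 0.83 ± 0.58 CPM (SD, n = 5), a log2 fold change of −3.89 with SE 0.47 (edgeR, adjusted p = 5.61e-04), from counts of 49 to 191 per vehicle library and 1 to 19 per monocrotaline library. ENSRNOG00000047307 fell from 4.84 ± 2.15 CPM (SD, n = 6) to 0.645 ± 0.510 CPM (SD, n = 5), a log2 fold change of −2.88 with SE 0.47 (edgeR, adjusted p = 0.00155), from counts of 29 to 93 and of 2 to 19. No tested feature was silent in 1 group and present throughout the other.

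**Figure D2:**
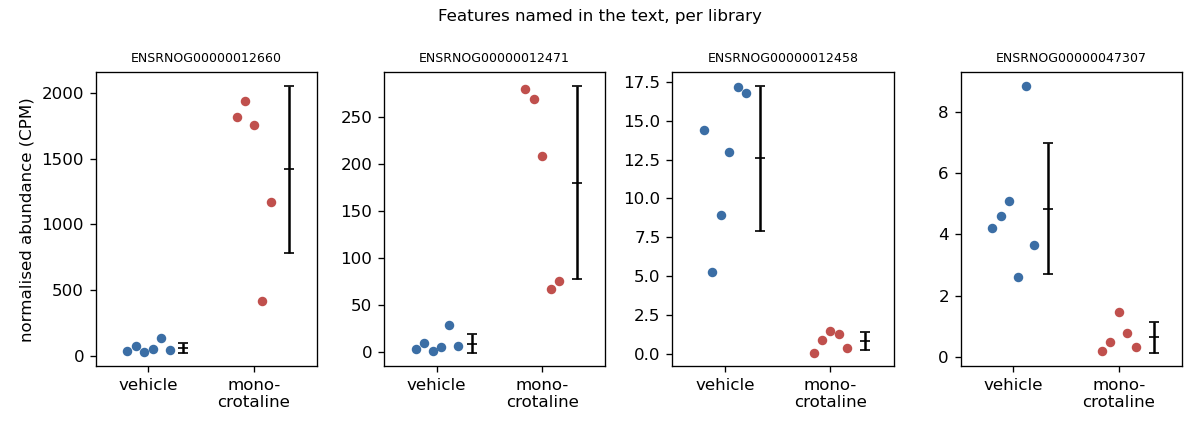
Normalised abundance in CPM of the 4 named Ensembl IDs in each vehicle library (blue, n = 6) and each monocrotaline library (red, n = 5), on linear axes. Black bars give the mean ± SD of each group, and the groups do not overlap in any of the 4 IDs.

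Features with an Ensembl ID changed more often upwards, and assembled loci more often downwards. Of 11138 tested Ensembl IDs, 1488 were higher and 1115 lower with monocrotaline by edgeR. Of 3961 tested assembled loci, 429 were higher and 563 lower. Changes of more than 4-fold were found in 87 higher and 35 lower Ensembl IDs, and in 31 assembled loci each way. The difference between these classes was not tested, since features are not independent replicates. The classes were not matched for abundance, with which the direction of change varied, as given below.

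Among the most abundant transcripts of the right ventricle, those that changed were more often lower than higher with monocrotaline. Among the 100 most abundant features, 36 were lower, 10 higher and 54 not called by edgeR, and 77 had a negative log2 fold change, with a median of −0.43. Of the features called after these and up to rank 500, 123 were lower and 52 higher, and at ranks 501 to 1500, 193 were lower and 136 higher. At ranks 1501 to 5000 there were 538 lower and 465 higher. Below rank 5000 the balance of the calls turned, with 788 lower and 1254 higher among 10099 features. The median log2 fold change of these 10099 features was only 0.019. Fewer of the same 100 features were called lower without monocrotaline replicate 2 (20, median log2 fold change −0.47), with no filter on low counts (22, median −0.42) and in the 8 libraries of lower detection (13, median −0.30), while 77, 77 and 75 of them had a negative log2 fold change. An FDR of 0.01 left 12 of the 100 lower and a minimum fold of 1.5 left 2, both by construction. With no normalization factor, 31 of the 100 were lower, and the median log2 fold change of the 100 was −0.25 against 0.21 for the other features.

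In the counts themselves, with no scaling factor, the 100 most abundant features took a smaller share of all reads with monocrotaline. Their share was 40.2% ± 1.59 with vehicle (SD, n = 6) and 33.8% ± 4.06 with monocrotaline (SD, n = 5), and every monocrotaline library lay below every vehicle library (exact two-sided permutation p = 0.00216, the smallest the 462 splits can give, and 0.00649 after Benjamini-Hochberg adjustment over 6 measures). The gap was narrow, with monocrotaline replicate 4 at 38.33% and vehicle replicate 2 at 38.41%. Without vehicle replicate 1 or without vehicle replicate 6, with the 100 features chosen anew, the exact permutation p was 0.0159. Without any other vehicle library it was 0.00794. The share of the 20 most abundant features was 24.8% ± 2.05 (SD, n = 6) and 18.9% ± 3.37 (SD, n = 5), with an exact permutation p of 0.00649 and an adjusted p of 0.0130. Within the 8 libraries of lower detection, the share of the 100 features was 39.7% ± 1.06 with vehicle (SD, n = 4) and 35.3% ± 2.34 with monocrotaline (SD, n = 4; exact permutation p = 0.0286, the smallest that 70 splits can give, which follows from the lack of overlap among all 11). For the 20 features the means within these libraries were 24.1% ± 1.75 (SD, n = 4) and 20.2% ± 2.04 (SD, n = 4), with an exact permutation p of 0.0571. The other 3 libraries, 2 vehicle and 1 monocrotaline, were too few for a test of their own.

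The libraries separated by treatment along the first principal component, which held 40.4% of the variance, and the second held 15.8%. On the score from 0% at the vehicle mean to 100% at the monocrotaline mean, the vehicle libraries lay between −5.55% and 28.2%. Monocrotaline replicates 1, 2, 3 and 6 scored 103%, 100.1%, 110.2% and 87.1%, and replicate 4 scored 38.3%. Replicate 4 was the monocrotaline library nearest the vehicle mean for 2508 of the 3595 called features, or 69.8%, where equal shares would be 20%.

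**Figure D3:**
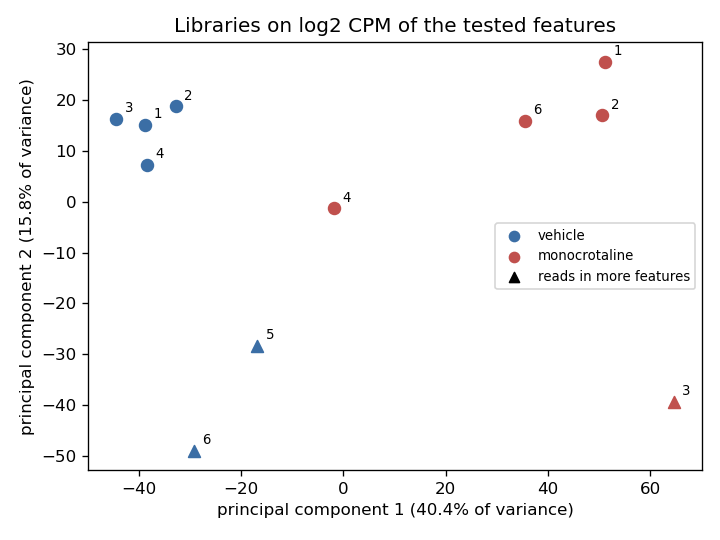
Each library on the first principal component (40.4% of variance) and the second (15.8%) of log2 CPM over the tested features, in arbitrary units, with its replicate number. Blue points are vehicle and red points monocrotaline libraries, triangles mark the 3 libraries with reads in more features, and monocrotaline replicate 4 lies between the groups.

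A second difference between libraries did not follow treatment. Vehicle replicates 5 and 6 and monocrotaline replicate 3 had reads in 28209, 30593 and 29846 features, against 19825 to 21524 in the other 8 libraries. Of 11234 features with no read in those 8, vehicle replicate 5 had reads in 4466, vehicle replicate 6 in 6135 and monocrotaline replicate 3 in 5431. These reads made up 0.124%, 0.370% and 0.285% of the totals, and the median count of such a feature, where present, was 2, 3 and 3. With this detection class as a covariate in edgeR, 2181 features were higher and 1957 lower with monocrotaline, and 351 features were higher and 28 lower in the 3 libraries themselves.

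**Figure D4:**
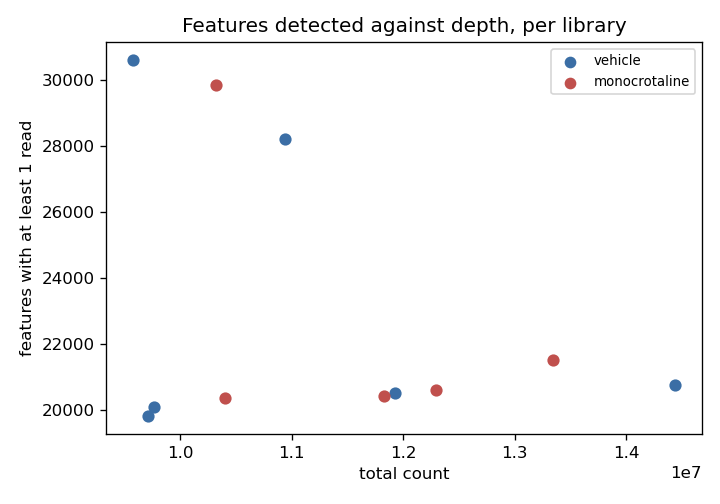
Number of features with at least 1 read against total count, one point per library, blue for vehicle and red for monocrotaline. The 3 libraries at 28209 to 30593 features do not have the highest totals, and the vertical axis does not start at 0.

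The authors' deposited table was set beside the edgeR result on the same counts. The authors' deposited table holds 1887 features higher and 1646 lower with monocrotaline at an FDR of 0.05. Of the 15091 features in both, 3400 were called in both, 97 only in the authors' deposited table and 195 only by edgeR, and 0 of the shared calls differed in direction. A further 36 calls of the authors' deposited table fell on features that the filter used here removed. Log2 fold changes differed by at most 0.08 between the authors' deposited table and edgeR.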

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

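All tests of an explanation in this part were chosen after the result was seen. A library was singled out when its gap to the nearest library of its group was large for the group's range, a rule that picks about 1 in 20 groups by chance. It picked 5 of 28 groups, and the measures are not independent of one another. Monocrotaline replicate 3 had reads in 29846 features, against 21524 for the next monocrotaline library. Reads in features silent in the libraries of lower detection made up 0.2847% of its counts, against 0.00554% for the next. That next library is itself of lower detection, so its value covers features silent in the others of that class. In vehicle replicate 6 they made up 0.3703%, against 0.124% for the next vehicle library. Among the vehicle libraries, replicate 6 also deviated most from the group mean, by 0.51469 in log2 CPM (root mean square), with the next vehicle library at 0.432. ENSRNOG00000012471 stood at 27.71 CPM in vehicle replicate 5, against 9.226 CPM in the next vehicle library.

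The reads in otherwise silent features of vehicle replicates 5 and 6 and monocrotaline replicate 3 were weighed against 3 technical explanations. Depth was argued against, since the highest total of the 3 libraries was 10940285 counts and the median of the other 8 was 11876618. Carry-over of reads was not decided. Of the features with no read in the 8, 29.6% had reads in all 3. These features were chosen for having no read in the 8, so the choice itself leaves out carry-over from those 8. Carry-over among the 3, or from libraries outside this set, was not tested. The reads were spread thinly: the top 1% of features held at most 8.36% of them in any of the 3 libraries, which is consistent with a diffuse background, possibly genomic DNA or unprocessed RNA, though thinly spread reads do not tell these sources apart. The labels give no batch, both treatments are among the 3 libraries, and no biological explanation was tested.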

How the results depend on the processing

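The alternatives with library totals alone, the authors' filter, the detection class and the 8 libraries of lower detection were chosen after seeing the data. Over 26 alternatives, the 4 named IDs kept their direction and an FDR under 0.05 in all 103 values that could be computed. The 4 IDs were chosen from these same libraries for large changes, a low FDR and groups without overlap. Their persistence was therefore largely set by that choice and is not independent support. In the alternative with a stricter FDR, the values of these IDs were those of the main fit. The stricter filter removed ENSRNOG00000047307. Under relative log expression, upper quartile or reduced TMM factors, DESeq2, limma-voom, the stricter filter, thinning, the authors' filter and the detection class, counts of calls stayed within 1.5 times. Leaving out each library gave 1447 to 2501 features higher, 1123 to 2330 lower and 2502 to 3442 calls shared with the authors' deposited table, and a share difference of the 100 most abundant features of −7.61 to −4.98 percentage points. The highest counts came without monocrotaline replicate 4, where 3508 of the 3595 calls were kept.

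With no filter, 33648 features were tested and 971 were lower. An FDR of 0.01 left 905 higher, 582 lower and 1487 shared calls, and a minimum fold of 1.5 left 338, 140 and 478, both by construction. The 8 libraries of lower detection gave 1087 higher, 653 lower and 1618 shared calls, with fewer samples, and 1609 of the 3595 calls were kept. Library totals alone gave 3541 higher and 986 lower, where the median log2 fold change moved to 0.21. The ratio of mean deviations, monocrotaline to vehicle, was 1.105, and turned to 0.867 with no filter and 0.936 with the authors' filter. The cause of these reversals and of the lower count with no filter was not tested.

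Same-numbered libraries deviated from their group means with correlations of 0.06, −0.03, −0.21, 0.16 and −0.20 across features. These values gave no sign of pairing. They cannot show that same-numbered samples share no litter or day, which the labels do not state. With a replicate block on the 10 libraries that share numbers, 1348 features were higher and 1231 lower, 2579 in all against 3172 without the block. DESeq2 gave no adjusted p for 28 features. The alternatives for the gene lists, including the estimated correlation and the self-contained set test, were not run, since no ID could be paired with a name. Depth limits the features of low count, such as the fallen IDs with 1 to 19 reads per monocrotaline library.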

Other observations

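The tests against other splits and for mixing with vehicle RNA were set out before their results were seen, and the other tests in this part were chosen only afterwards. Of 100 splits into groups of 5 and 6, 1 gave as many calls as the real one, which was the real split itself with 3595, and the highest of the others gave 844. These were 100 of the 462 possible splits, and the other splits mix the treatments within a group. Chance is an unlikely source of the count, but it was not excluded. That split of 844 calls put 5 vehicle libraries against all others, but another of the same make-up gave 0, and the median over the other splits was 0.

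Monocrotaline replicate 4 lay nearer to vehicle than the other monocrotaline libraries. The rule for large gaps, applied to the score as well, did not single it out. A swap between the groups was argued against, since it needs a vehicle library placed among the monocrotaline libraries. The highest vehicle score was 28.2%, in vehicle replicate 5, below the 38.3% of monocrotaline replicate 4. Vehicle replicate 5 still leaned towards monocrotaline, as the next vehicle score was 13.3%. A vehicle library wrongly labelled as replicate 4 was argued against only in part, by features called without replicate 4 and changed at least 2-fold. It lay beyond every vehicle library on the side of the change in 54.1%, where equal chances would give 14.3%. A vehicle library held out in the same way did so in at most 38.8%, where equal chances would give 16.7%. That was vehicle replicate 5, and the next was vehicle replicate 2 with 24.4%. Rank correlations over all tested features leaned slightly the other way. For monocrotaline replicate 4 they ran from 0.960 to 0.973 with the vehicle libraries. With the other monocrotaline libraries they ran from 0.945 to 0.972. Wrong labelling was therefore not excluded. Mixing of monocrotaline replicate 4 with vehicle RNA stays open. In features called without it and changed at least 2-fold, its CPM covered a median of 0.299 of the rise in 882 risen features. The median was 0.394 of the fall in 714 fallen ones, a difference of −0.0948, where the difference reached 0.36 in another monocrotaline library. The interquartile ranges of 0.330 and 0.451 were wider than the 0.1 set for an even mixture, but every other monocrotaline library also exceeded 0.1, so they do not decide. A weaker response in that sample may also be the source and was not tested.

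The smaller share of the 100 most abundant features with monocrotaline might come in part from the 3 libraries with reads in more features. With the 100 features chosen in the other 8 libraries, the difference was −4.36 percentage points, against −6.46 over all 11. The shares of those 3 libraries, with the features chosen over all 11, had no common direction. Vehicle replicate 6 had the highest share of all libraries at 43.0%, and vehicle replicate 5 stood at 39.6%. Monocrotaline replicate 3 had the lowest share, at 27.5%. Reads in more features thus did not go with a smaller share throughout. The part of those 3 libraries in the difference cannot be told apart with 1 monocrotaline and 2 vehicle libraries of that kind. A change in the make-up of the tissue or in the transcription of its main cell type stays open and was not tested.

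The monocrotaline libraries deviated from their group mean by 0.483 ± 0.0692 in log2 CPM (root mean square, SD, n = 5) and the vehicle libraries by 0.437 ± 0.0408 (SD, n = 6). A graded response to treatment could widen the monocrotaline group along the line between the group means. The ratio of the mean deviations was 1.105, and 1.053 with that line removed, but the direction of the ratio turned with the filter on low counts, so this test decided nothing.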
